A study of Oncorhynchus mykiss with 7 samples.

How the data were processed

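Skin RNA of rainbow trout was measured on 7 oligonucleotide microarrays with 2 dyes. Per the labels, each array carried RNA from an infected fish in the Cy5 channel and control skin RNA in the Cy3 channel, and the 7 arrays are biological replicates numbered 1 to 7. The infected fish had received an injection of Aeromonas salmonicida into the body cavity, per the labels' protocols. The labels do not say how long after the injection skin was taken, or whether the control RNA was a single pool or came from separate fish.

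The authors deposited 1 table of normalized log ratios with a value per spot and array. The unit was read as log2: the table runs from -7.41 to 7.35, a range too wide for log10 ratios of scanner signals. Agilent Feature Extraction 10.10.1.1 and limma are named in the submitters' processing notes, without their roles, and limma reports log2 of red over green. The direction was therefore taken as infected over control, from the dyes in the labels; the file headers state neither the log base nor the direction. Background correction, within-array normalization and any filter are not given in the sources used here. Normalized ratios are relative to the typical probe of each array, so a change shared by most transcripts would not be seen. Channel signals were not used here, so no probe can be called dim or saturated, and ratios of transcripts close to background cannot be told from ratios of abundant ones. With arrays, the number of arrays limits the precision.

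The table held 43628 spots with 0 missing values. A total of 21754 probe identifiers had 2 spots each, and 12 identifiers named RC followed by a number had 10 spots each. What RC stands for is not given; these identifiers were kept out of the counts and served as a background. The last line of the file placed replicates 1 to 4 on one slide (slide 1) and replicates 5 to 7 on another (slide 2). The columns carried the replicate numbers of the sample titles and were matched on them.

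The identifiers begin with Omy# (18169) or Ssa# (3585) followed by sequence or clone codes, and the files pair none of them with a gene name. Of the 21754 identifiers, 0 matched an entry of a reference table of 72772 rainbow trout genes. The 34 gene lists and cell type markers that had been fixed before the data were examined could therefore not be tested, and 0 of them were. For the same reason no gene is named, and the rule for naming genes, which ranked named genes by their mean ratio among those past the threshold with the same sign on all 7 arrays, was applied to probe identifiers and limited to the first 2 that rose and the first 2 that fell. Identifiers are not independent genes, since several can represent the same transcript.

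The 2 spots of each probe were averaged. An intercept-only linear model was fitted to the 7 log2 ratios of each probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and the mean was tested against 0, two-sided, with Benjamini-Hochberg adjustment over the 21754 probes and a threshold of 0.05. If the control RNA was a single pool, this test leaves out the spread between control fish. The effect of this was simulated after the results were seen, with normal values for 7 unchanged fish minus 1 shared control sample, each with the SD between arrays of the real probe. That SD includes technical noise, and a pool of many fish would deviate less. No array had its dyes exchanged, per the labels, so an effect of the dyes on a probe has the same direction as an effect of infection. On simulated data with the spread of the real probes, the fit recovered 87% of 200 probes changed by 1 log2 unit with 10 false calls, and 97% of 200 probes changed by 2 log2 units with 7 false calls, among 21754 probes in each case. Smaller changes were not simulated, though 65.1% of the probes called in the real data lay below 0.5 in size. The simulated probes were independent and carried no dye or control effect, so these rates do not describe most of the calls.

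Alternatives fixed before the data were examined were centring, scaling or quantile normalization of the arrays, array weights, a robust variance prior, a plain one-sample test per probe, a stricter adjusted p, a fold threshold, a restriction to complete probes and leaving out each array in turn. The slide as a random block, each slide alone, and the first or second spot of each probe alone were added after seeing the data. The filter on dim probes and the probe summary by highest signal were not run because they need signals.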

Results

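The series compared skin from rainbow trout infected with Aeromonas salmonicida, the bacterium that causes furunculosis in salmonids, with control skin. Each of 7 arrays gave the log2 ratio of infected over control RNA for 21754 probes with 2 spots each. The paired spots correlated with Pearson r between 0.929 (replicate 4) and 0.981 (replicate 2) across probes. The spot-to-spot SD within an array lay between 0.0858 (replicate 2) and 0.134 (replicate 4) log2 units. The 12 RC identifiers, averaged over 10 spots per array and so less noisy than the probes, stayed close to 0: their means over 7 arrays ran from -0.035 to 0.0046, and no single array value exceeded 0.092 in size. With limma, 0 of the 12 passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05, whereas a plain one-sample test passed 1 after adjustment and 2 before it.

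The first question was which transcripts differed in skin after infection. Of the 21754 probes, 2036 were higher and 1850 were lower in infected skin (limma, adjusted p under 0.05, n = 7 arrays), together 17.9% of the probes. Whether the arrays shared a control RNA is not given. In a simulation without an effect of infection, fish set against 1 shared control sample gave 6268 called probes, more than observed. That sample was given the whole SD between arrays, noise of single arrays included, so 6268 is likely too high for a real control. By themselves the observed counts do not show an effect of infection, since part of them could come from a shared control. These counts depended on single arrays: without replicate 4 they were 991 and 931, and without replicate 1 they were 1115 and 1103. The higher probes were also fewer by over 1.5 times without replicate 3 (1318) or 5 (1340), and the lower probes without replicate 2 (1143) or 3 (1208). On slide 2 alone (3 arrays) 0 and 2 were called. Most of these changes were small: the median rise was 0.37 log2 units (1.29-fold), the median fall 0.33 (1.26-fold), and 65.1% of the called probes lay below 0.5 in size. Of the called probes, 1627 rose and 1455 fell with the same sign on all 7 arrays. A change of at least 1 log2 unit was seen for 257 probes that rose and 193 that fell.

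Among the called probes, the rises outnumbered the falls most at large changes. At 2 log2 units or more (4-fold), 63 called probes were higher and 17 were lower. At 3 units or more the numbers were 22 and 1, and at 4 units or more they were 8 and 0. Leaving out 1 array at a time gave 45 to 94 probes at least 4-fold higher and 8 to 23 at least 4-fold lower, and the rises outnumbered the falls each time. In the simulation with 1 shared control sample and no effect of infection, 85 probes were called at least 4-fold higher and 77 lower. That simulation treats both directions alike, so its near balance is built in. Over all probes, called or not, and by single arrays instead of means, the directions were close to balance. On at least 1 array 528 probes were over 2 and 506 under -2. Replicates 6 and 7 had more probes under -2 (192 and 201) than over 2 (50 and 141). Replicates 1 to 5 each had more over 2, from 114 against 94 on replicate 4 to 251 against 134 on replicate 2. Higher and lower rest on reading the ratio as infected over control, from the dyes in the labels; with the opposite reading they would exchange places. The lowest count of falls, 8, came without replicate 4, and there were 11 without replicate 1 or without replicate 7. On the 3 arrays of slide 2 alone, 0 probes were called at least 4-fold higher and 2 at least 4-fold lower. Of these 2 probes, 0 were among the falls called on 7 arrays.

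The largest consistent rise belonged to probe Ssa#S35499883, whose mean log2 ratio was 5.10 ± 1.21 (SD, n = 7; SE 0.41), a 34.3-fold difference with a limma adjusted p of 0.0027. Its lowest value was 3.34, on replicate 6, and its highest 6.80, on replicate 2, and it was the only probe of the 21754 above 2 on all 7 arrays. Probe Omy#S21947975 followed with 4.89 ± 1.93 (SD, n = 7; SE 0.66; limma adjusted p 0.0065). On 6 arrays this probe lay between 4.62 and 6.05, and on replicate 6 it was 0.65; without replicate 6 its mean was 5.60. The largest consistent fall belonged to Omy#S22928763 at -3.40 ± 1.64 (SD, n = 7; SE 0.56; limma adjusted p 0.0097), with values from -6.01 on replicate 2 to -1.29 on replicate 3. Omy#S21809075 was at -2.77 ± 0.88 (SD, n = 7; SE 0.30; limma adjusted p 0.0046), from -3.62 on replicate 3 to -1.11 on replicate 2. The 2 spots of these probes differed by at most 0.41 on any array.

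**Figure D1:**
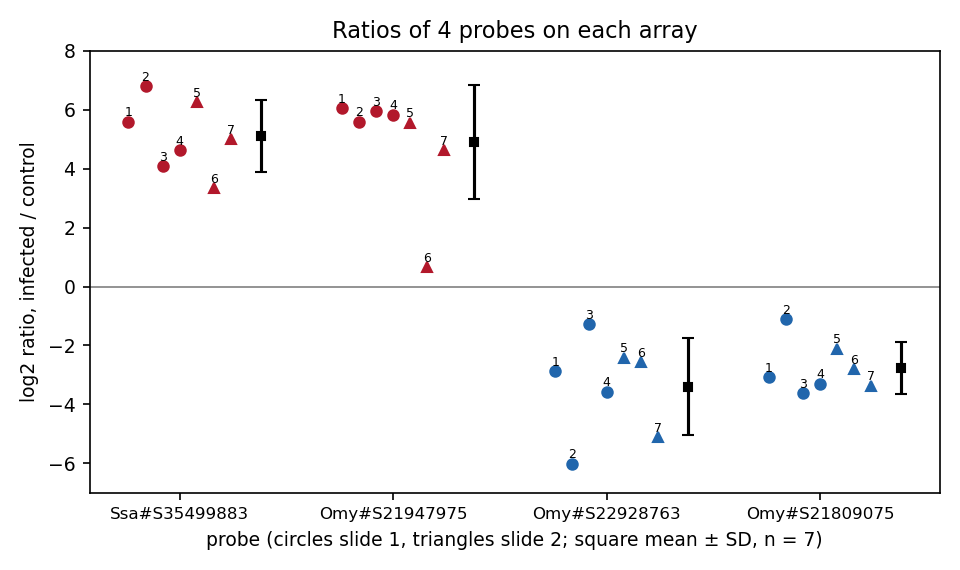
Log2 ratio of infected over control skin RNA (vertical axis) for the 4 probes with the largest rises and falls that had the same sign on all 7 arrays; numbers are replicates, circles slide 1, triangles slide 2, and squares the mean ± SD (n = 7). Replicate 6 lies at 0.65 for Omy#S21947975, whose other 6 values lie between 4.62 and 6.05.

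The second question was how alike the 7 infected fish were. Among called probes the median SD between arrays was 0.190. It includes differences in labelling, hybridization and possibly control RNA as well as between fish, while the median noise of the mean of 2 spots on an array was 0.066. Pearson r between arrays, across probes that are not independent replicates, ranged from 0.038 (replicates 2 and 6) to 0.798 (replicates 1 and 4) with a median of 0.43. Replicates 1 and 4 were counted as separate samples, as labelled. The SD of their difference across probes was 0.318, against 0.121 from spot noise alone. This shows separate hybridizations, but not by itself separate fish. The counts of called probes fell most when replicate 4 or replicate 1 was left out. A log2 ratio over 1 occurred on at least 1 array for 2275 probes and on all 7 arrays for 4. A ratio under -1 occurred on at least 1 array for 2054 probes and on all 7 for 11. In 576 probes the ratio was over 1 on one array and under -1 on another.

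The arrays also differed in how many probes moved strongly. Replicate 2 had 981 probes over 1 and 790 under -1, whereas replicate 4 had 477 and 509. Replicate 6 had the fewest probes over 2, with 50 against 114 to 251 on the other arrays, but 192 under -2, where the other arrays had 93 to 201. To compare arrays without using an array's own values for the choice, probes were picked by their mean on the other 6 arrays. Probes with a mean over 1 on the other arrays had a median of 1.17 to 1.68 on replicates 1 to 5 and 7, and of 0.14 on replicate 6 (399 probes, interquartile range -0.21 to 0.55). Probes with a mean under -1 on the other arrays had a median of -1.18 on replicate 6 (335 probes, interquartile range -2.33 to 0.026), within the range of -1.28 to -0.42 on the other arrays.

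**Figure D2:**
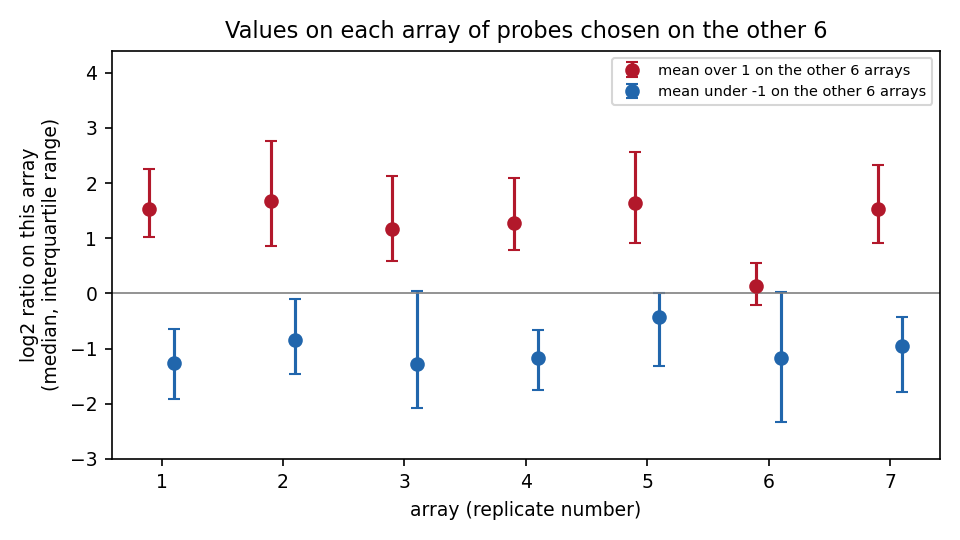
Median log2 ratio with interquartile range (vertical axis) on each array (horizontal axis) for probes chosen by a mean over 1 (red) or under -1 (blue) on the other 6 arrays. The red median is 0.14 on replicate 6 and at least 1.17 on every other array, while the blue median on replicate 6 is -1.18.

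Arrays on the same slide were not detectably more alike than arrays on different slides. The mean r was 0.42 for the 9 pairs on the same slide and 0.40 for the 12 pairs on different slides (exact two-sided permutation test over the 35 splits of the arrays, p = 0.771). With limma, 0 probes differed between the slides at an adjusted p under 0.05, and 904 (4.16%) had an unadjusted p under 0.05. Within slide 1 alone (4 arrays), limma called 479 probes higher and 640 lower, and of these 1119 probes 1072 (95.8%) had the same sign on slide 2. Within slide 2 alone (3 arrays), 0 probes were called higher and 2 lower, with 1525 and 1174 at an unadjusted p under 0.05. The mean ratios of the slides correlated with Pearson r = 0.71 across probes. In the simulation with 1 shared control sample and no effect of infection, 97.3% of the probes called on slide 1 had the same sign on slide 2 and r was 0.78. The covariance of the slide means was 0.117 as observed and 0.173 as simulated. The simulated agreement follows from the spread given to the control sample, which was larger than the observed covariance allows. Agreement of the slides cannot separate infection from a shared control RNA, since either would produce it.

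**Figure D3:**
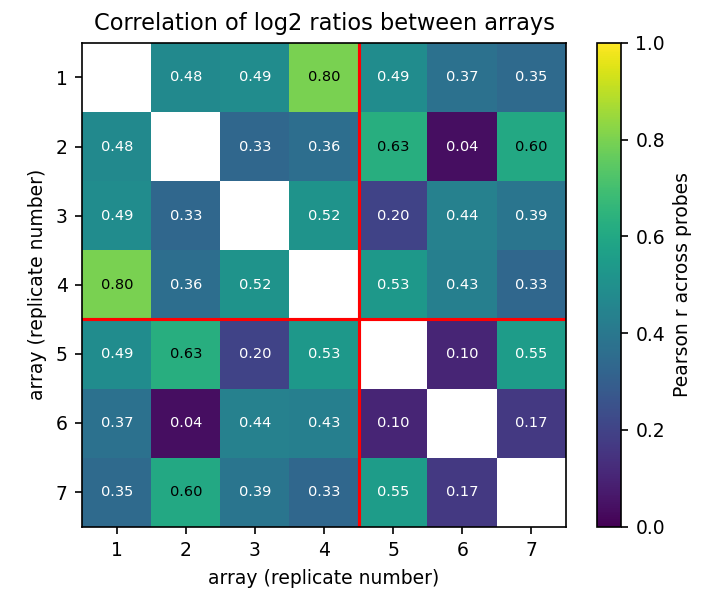
Pearson r of log2 ratios across 21754 probes for each pair of arrays (both axes, replicate numbers), with red lines between slide 1 (replicates 1 to 4) and slide 2 (replicates 5 to 7). The highest value, 0.80, joins replicates 1 and 4, and the lowest, 0.04, replicates 2 and 6.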

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

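The tests of control RNA in both channels, of a skin sample with little response, of a control RNA shared by all arrays and of dye bias in the large rises were chosen after the results were seen; the tests of sign patterns, swapped dyes and compressed ratios were written before. Of 14 values per array checked for an array standing apart, 3 did so. Independent normal values would give about 1 in 20, but the same check flagged 8.51% of all probes. The 14 values also overlap, since Omy#S21947975 is one of the rises whose median was checked. Whether 3 exceeds chance was therefore not measured.

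Replicate 6 stood apart in Omy#S21947975, at 0.65 with the nearest other array at 4.62, and in the median of the probes chosen as rises on the other arrays, at 0.14 with the nearest at 1.17. Replicate 2 stood apart in the number of probes over 1, with 981 against 663 on the next array. Of the 257 called probes at least 2-fold higher, 41 had an array standing apart, and in 36 of them it was replicate 6 on the low side. Over all 21754 probes, 1852 (8.51%) had an array standing apart, and replicate 6 was that array in 292, fewer than replicate 7 (443) or replicate 2 (416). Among the 193 called falls of that size, 13 had such an array, and in 3 it was replicate 6.

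For the weak rises of replicate 6, a compression of all ratios on that array would shrink rises and falls alike. The median share retained was higher for falls than for rises by 0.802; the interquartile ranges of the shares overlapped, so the criterion set in advance was not met, but an array compressed to the level of its rises could not hold 192 probes under -2, against a mean of 126.5 on the other arrays. The same control RNA in both channels would leave dye effects, which the other arrays share; 115 of the 192 probes had a median over -1 on the other arrays, which argues against it. That share, 59.9%, is not particular to replicate 6, since the same tally gave 31.2% (replicate 1) to 75.1% (replicate 7) elsewhere, and without the 35 probes low on replicates 3, 6 and 7 it was 80 of 157. Those 35 probes count here, since the same RNA on both sides cancels whatever the control RNA held, and their median on replicate 6 was -4.06. A skin sample that held little of the response at the time of sampling remains open as a hypothesis (median of the rises 0.136, or -0.0067 for probes with a mean over 2 on the other arrays), since the labels give no bacterial load per fish. An uninfected fish in the Cy5 channel also remains open, because such a fish can differ from the control RNA on its own. Against it stand the probes chosen as falls on the other arrays, with a median of -1.18 on replicate 6 (share retained 0.88). If the control RNA was shared, these falls could come from it and decide nothing. Probe Ssa#S35499883 was still at 3.34 on replicate 6, but it was picked by a mean and a sign that include replicate 6. It therefore does not count against an uninfected fish.

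The number of called probes was set against the 64 ways of exchanging the sign of arrays, each counted once with its mirror. The real signs gave 3886 called probes and the highest other pattern 26, so 1 of 64 patterns reached the real count, which argues against chance values that are independent between arrays. What this test does not address is a cause shared by all arrays. Unchanged fish set against 1 shared control sample gave 6268 called probes in a simulation. By this count, a control RNA shared by all arrays cannot be told apart from infection. The labels do not say whether the control RNA was shared. A pool of many fish would give fewer called probes, as would a control sample without the noise of single arrays. Dye effects may account for part of the small changes that had the same sign on all 7 arrays, and 0 arrays had exchanged dyes, so dye and infection cannot be told apart for these. For the probes chosen as rises on the other 6 arrays, a dye effect alone would be as large on replicate 6, where their upper quartile was 0.549; this argues against dye as the whole source of those rises, on the evidence of 1 array. A shared control RNA would also recur on replicate 6. For probes chosen in the same way in the simulation, the lowest upper quartile on a left-out array was 2.03. Replicate 6 lay below this. All simulated arrays were drawn alike, so none could stand apart, and the control sample had a larger spread than the observed covariance allows. The comparison, which also rests on 1 array, therefore cannot decide whether a shared control made these rises.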

How the results depend on the processing

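Centring, scaling, quantile normalization, array weights, a robust prior, the plain one-sample test and either spot alone gave 1577 to 2296 probes higher and 1501 to 2173 lower, within 1.5 times of the reported 2036 and 1850; no value was missing, so the restriction to complete probes removed nothing. Leaving out 1 array gave 991 to 1582 higher and 931 to 1513 lower. The count of higher probes fell by more than 1.5 times without replicate 1 (1115), 3 (1318), 4 (991) or 5 (1340), and that of lower probes without replicate 1 (1103), 2 (1143), 3 (1208) or 4 (931); fewer arrays enter each of these fits. An adjusted p under 0.01 left 431 higher and 463 lower, and a change of at least 1 log2 unit left 257 and 193. Slide as a random block, added later, gave 3486 and 3287, with a negative correlation within slides of -0.12 that narrows the standard errors; slide 1 alone gave 479 and 640 and slide 2 alone 0 and 2, with 4 and 3 arrays. Called falls of at least 4-fold, 17 as reported, numbered 11 with the plain one-sample test and 27 with the slide block. The 4 probes given by identifier kept their direction under all settings run and passed the threshold except within a slide: on slide 2 alone the adjusted p was 0.29 to 0.39 for all 4, and on slide 1 alone it was 0.097 for Omy#S22928763 and 0.054 for Omy#S21809075. No paired analysis was possible because there is a single group and each ratio already sets infected against control RNA on one array. The unknown background correction limits the ratios of dim probes.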

Other observations

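The test of control RNA that differed between arrays was chosen after the results were seen; the tests of spots and slides were written before. Some probes fell into separate sets of arrays instead of varying by degree. With a gap of at least 2 log2 units and at least 2 arrays on each side, 95 probes split in this way. Normal values with each probe's own mean and SD gave 73. The SD of a split probe is itself widened by the split, so 73 does not measure how many splits chance would give. What stands out is which arrays were parted: 36 of the 95 probes (37.9%) set replicates 3, 6 and 7 against replicates 1, 2, 4 and 5, where equal use of the 56 possible partitions gives 1.79%. Equal use is a rough yardstick, because some pairs of arrays were more alike than others. Several of these probes can also represent the same transcript, so they are not independent. In 35 of these probes replicates 3, 6 and 7 were low, with medians of -4.01, -4.06 and -3.50, while the medians on replicates 1, 2, 4 and 5 were -0.14, -0.038, -0.084 and 0.0047. With limma, 0 of the 35 passed an adjusted p of 0.05 and 24 had an unadjusted p under 0.05.

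Spot defects are argued against, since the 2 spots taken alone gave the same set of arrays in 86.3% of the split probes, under the 90% set in advance, and another set in 0%; in the rest a spot had a gap under the limit. The slides parted the arrays in this way in 0% of the split probes, which argues against a slide batch. A hypothesis is that these transcripts were present in the control RNA of replicates 3, 6 and 7 alone and near background in both channels elsewhere, which might place the ratio at 0; the largest median on the other arrays was 0.139 in size. This lies outside the RC values, which stayed within 0.092, and single probes ran from -1.08 to 1.22 on those arrays, so not all lay near 0. Equal levels in infected and control RNA would give similar values, and ratios without channel signals leave these open. No biological explanation was tested, because the labels give no property that differs between the fish.

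The identifiers beginning with Omy# and Ssa# had similar shares of called probes, with 17.9% of 18169 and 17.5% of 3585. The median SD between arrays was 0.177 for Omy# and 0.117 for Ssa# identifiers; this difference was not tested.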
